A study of Mus musculus with 2 samples.

How the data were processed

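H3K27ac ChIP-seq peaks of mouse forebrain at embryonic day 10.5 were analysed from 4 deposited peak lists. The labels give 1 group with 2 biological replicates, which are separate pools of 69 and 51 embryos. The p-values that compare the replicates come from the spread across genes or peak positions. They do not measure the spread between libraries. Per the deposited file notes, one list was derived from the alignments of replicate 1, one from those of replicate 2, one from both together (pooled peaks) and one from the pooled list and both replicate lists (replicated peaks). The same notes give the list of replicate 1 and the pooled list 2 further input files, and the list of replicate 2 only 1 of them. Whether these are control libraries, and whether the difference is one of record keeping, is not given in the sources used here. The genome build is mm10 per the labels. The aligner, the peak caller and the rule for calling a peak replicated are not given in the sources used here.

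Each list is in the narrowPeak format, per the deposited file notes. Each peak has a score, which the authors scaled for display and which was not used here. It has a fold enrichment, a ratio of signal over control as the authors' peak caller gave it. The lists also hold the deposited −log10 of the p-value and of the q-value of each peak. No deposited p-value exceeds 0.01, so the lists were called at a relaxed limit, and 80.5% of replicate 1 peaks, 74.7% of replicate 2 peaks and 99.0% of replicated peaks reach a −log10 q of 2. The deposited summit offset placed each peak's summit. All replicated peaks have the bounds of a pooled peak, so their fold enrichment is that of the pooled data. The fold enrichment was used to describe and rank peaks within a list. The files give no read counts or library sizes, so the depth of each replicate is unknown and no interval that needs it is given. The number of peaks also depends on depth, so the lists' lengths show no difference between the embryos.

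Coordinates are those of mm10 as deposited, printed from 1. Genes came from GENCODE M21 and sequence from the GRCm38.p6 assembly, the same build as mm10, and no peak lay past a chromosome end. The 21938 protein-coding genes on chromosomes 1 to 19, X and Y were used with 54446 TSSs of their protein-coding transcripts. Peaks on scaffolds, 10 in the replicated list, entered no comparison. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1 indexed the genome.

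The tests, the alternatives, the rule for named genes, 21 gene lists and 18 motif consensus sequences were fixed before the data were examined, and a list of all olfactory receptor genes was formed by symbol. The lists were neural progenitor, forebrain identity, pallium, subpallium, diencephalon with hypothalamus and optic vesicle, midbrain and hindbrain, Hox, patterning signals, newborn neuron, mature neuron and synapse, glia, neural crest and mesenchyme, surface ectoderm and epithelium, endothelium, erythroid, myeloid, liver, heart, skeletal muscle, cell cycle and housekeeping. Of their symbols 1, in the erythroid list, was not in the annotation, and 9 genes stood in more than 1 list. Named genes are the 3 members of each list with the highest promoter fold enrichment, the first 3 members without a replicated promoter peak, the 10 genes with the most distal peaks, the genes with a TSS in the 10 widest domains, and the genes nearest the 10 strongest replicated peaks and the 5 strongest peaks private to each replicate. Where a text names another gene to illustrate a result, it was chosen after its values were seen.

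Overlap between replicates required at least 50% of the length of either peak and was set against 100 shuffles of positions within chromosomes that avoided assembly gaps of 10 kb or more. A gene was called marked where a replicated peak overlapped 1 kb to either side of any of its TSSs, and lists were compared with all other protein-coding genes by Fisher's exact test. Promoter strength was the highest fold enrichment at a marked promoter, compared with 10000 random lists of marked genes. Distal peaks overlapped no such window and were assigned to the gene of the nearest TSS within 100 kb of the summit, and counts were compared with 10000 random lists matched on 10 bins of territory length. The smallest two-sided p of these permutation tests is 0.0002 before adjustment. A marked promoter may share its peak with a neighbouring gene. Domains were formed from replicated peaks at most 10 kb apart. Motifs were searched on both strands, and the flank of each peak was drawn by a fixed seed from the sides free of pooled peaks. Benjamini-Hochberg adjustment ran over the lists or motifs of each test, with a threshold of 0.05. Genes, peaks and windows are not independent replicates.

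Marking, means of random lists, peak overlap, motifs, distal assignment, domains and the exact test between replicates were tested on simulated data with known answers. Peak location, the correlation of fold enrichments, the medians used for promoter strength, and the later tests of promoter ranks and of chromosome X were not simulated. For marking, only depletion was planted. In simulated marking of 21938 genes, 100% of lists with planted depletion were called and 1.33% of lists at chance. With random lists matched on territory, 96.7% of lists with values raised 3-fold were called and 3.33% of lists at chance, against 14.7% at chance without matching. A known share of common peaks was recovered within 0.63 percentage points, and a motif planted in 20% of 4000 windows was called in 100% of 5 runs, against 1.18% of motifs at chance. The simulated peak and background windows had the same base composition. Real peak windows and flanks differed in GC content (51.1% and 45.0%), so the share at chance does not carry over to them. The domain test passed 0.05 in 100% of 20 runs with planted genes and in 10% of 20 runs at chance. The test between replicates called 91.7% of lists whose members kept 40% of their marks in 1 replicate and 0% of lists at chance.

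The alternatives covered stricter peaks, other overlap rules, the pooled list, each replicate's own strongest peaks in place of the replicated list, other promoter windows, distances and stitching, random lists matched on promoter CpG content, and other backgrounds for motifs. Chosen after seeing the data were the use of only replicated peaks overlapped by both replicates' lists, of only domains with a protein-coding TSS, of distal peaks away from the TSS of any annotated gene, and the match on CpG content for promoter strength.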

Results

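Acetylation of lysine 27 of histone H3 (H3K27ac), a chromatin mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of mouse embryos of strain B6NCrl at embryonic day 10.5. All libraries belonged to 1 group with 2 biological replicates, made from pooled forebrains of 69 embryos (replicate 1) and 51 embryos (replicate 2) of both sexes. The deposited lists held 146205 peaks for replicate 1 and 134999 for replicate 2. A further list called on both replicates together held 189082 pooled peaks, of which the authors listed 88204 as replicated. The replicated peaks had a median width of 616 bases and covered 85.0 Mb, or 3.12% of the mm10 genome. The peak lists give no read counts, so the sequencing depth of each replicate is unknown. Each fold enrichment given here is the authors' value for that peak in its own list, and values of the replicates come from their separate lists. With a single group, the comparisons concern the agreement of the replicates and the position of the peaks relative to genes.

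Strong H3K27ac peaks recurred in both replicates, and weak ones mostly did not. Among the 20000 peaks with the highest −log10 p, 87.3% of those of replicate 1 and 88.6% of those of replicate 2 overlapped a peak among the other replicate's 20000 over at least 50% of the length of either peak. When all peaks were used, 51.9% of replicate 1 peaks were overlapped by replicate 2, against 4.58% after replicate 2 peaks were shuffled within chromosomes. The reverse share was 59.6%, against 4.96% after shuffling. The one-sided permutation p was 0.0099 in each case, the smallest that 100 shuffles can give. The share fell from 99.99% in the strongest 10% of replicate 1 peaks to 22% in the weakest 10%, and from 99.99% to 30.4% in replicate 2. Mean peak width fell alongside, from 2114 to 230 bases in replicate 1 and from 1977 to 234 in replicate 2. Strength and width were not separated. Of the pooled peaks, 46.6% were in the replicated list, from 100% of the strongest 10% to 3.02% of the weakest. Across the 73175 replicated peaks overlapped by at least 1 base in both replicates, the fold enrichments had a Spearman's rho of 0.742 and a Pearson's r of 0.924 on the log2 scale, and 1.42% of peaks lay more than 2-fold apart. These correlations run across peaks, which are not independent replicates. Replicated peaks without a peak in 1 of the replicates did not enter. Fold enrichments also span a narrow range, with quartiles of 2.59 and 3.84 over all replicate 1 peaks and 2.67 and 3.95 over all replicate 2 peaks. The small share more than 2-fold apart thus partly follows from this selection and does not measure how often the replicates disagree. Of the 88194 replicated peaks on the chromosomes, 82.6% were overlapped by peaks of both replicates' own lists over at least 50% of the length of either peak, and 0.543% by neither. Of the other 100876 pooled peaks, 0 met that rule in both lists. The replicated list was itself made from the replicate lists. This overlap therefore follows largely from its construction and is no separate evidence of agreement.

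**Figure D1:**
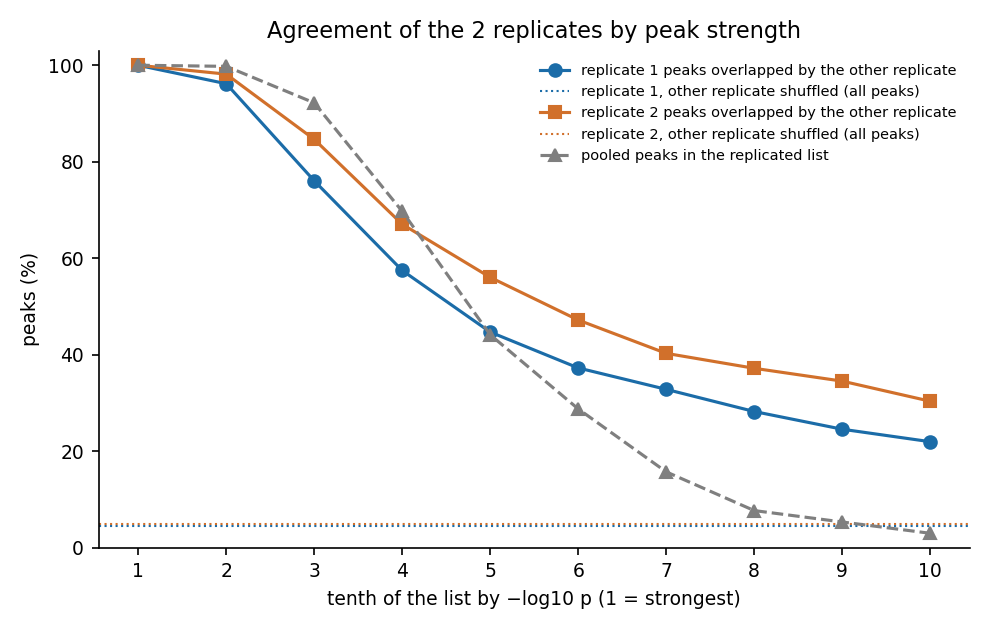
The percentage of peaks (vertical axis) is plotted against 10 equal bins of each list by −log10 p (horizontal axis, 1 being the strongest) for replicate 1 peaks overlapped by replicate 2, replicate 2 peaks overlapped by replicate 1, and pooled peaks in the replicated list, with dotted lines for all peaks against shuffled positions. The replicates' shares decrease from 99.99% in the strongest bin to 22% and 30.4% in the weakest, against 4.58% and 4.96% for peaks of all bins together with shuffled positions.

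Replicated peaks were concentrated at promoters and depleted between genes. The summits of 15890 peaks (18.0%) lay within 1 kb of a transcription start site (TSS) of a protein-coding gene, 6.79 times the 2.65% of shuffled peaks. Exons held 7.11% of summits against 4.45% of shuffled ones, introns 43.7% against 42.2%, and intergenic sequence 31.2% against 50.7%. The two-sided permutation p was 0.0198 for each location, the smallest that 100 shuffles can give. The small excess in introns became 41.9%, below the shuffled share and no longer past the threshold (permutation p = 0.119), when only replicated peaks found in both replicates' lists were used. Promoter peaks had a median fold enrichment of 13.1 and a median width of 1465 bases, against 3.10 and 540 bases in introns. The 10 peaks with the highest fold enrichment, from 54.2 to 58.9, had as their nearest protein-coding genes Kmt5b, Ddx6, Tnpo1, Zfp532, Arrdc3, Lmnb1, Pcif1, Setd1b, Zc3h4 and Epc1. The strongest lay at the promoter of Kmt5b, a histone H4 lysine methyltransferase gene (chromosome 19, 3766609 to 3769386). The peak at Lmnb1, which encodes lamin B1, reached 55.3 (chromosome 18, 56706552 to 56710162). Of these 10 summits, 9 lay within 1 kb of a TSS, and that at Setd1b lay in an exon 3.26 kb from it.

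Every member of 4 forebrain gene lists carried a replicated peak within 1 kb of a TSS. This held for 18 neural progenitor genes, 15 forebrain identity genes, 17 genes of the pallium (the dorsal telencephalon) and 18 genes of the subpallium (the ventral telencephalon), against 66.2% of all 21938 protein-coding genes (adjusted exact p = 0.00188, 0.00751, 0.00260 and 0.00188, Fisher's exact test, two-sided, Benjamini-Hochberg over 22 lists). Random lists matched on promoter CpG content were themselves marked at 93.0% to 96.7%, so that even full marking could not pass against them (adjusted permutation p = 0.580, 0.918, 0.918 and 1), and that comparison does not decide whether the marking exceeds that of promoters of like CpG content. Among neural progenitor genes the highest promoter fold enrichments were 52.5 at Msi1, an RNA-binding protein gene of neural stem cells, 42.4 at Cdh2, which encodes N-cadherin, and 41.5 at Zic2. Their values in the separate lists were 46.3, 39.1 and 38.8 in replicate 1 and 45.5, 40.04 and 32.8 in replicate 2. Forebrain identity genes were led by Nr2f1 at 45.3, Emx2 at 43.5 and Zic5 at 41.5. Pallial genes were led by Gli3 at 46.6, Emx2, and Pax6 at 41.2, all transcription factor genes of cortical patterning. Subpallial genes reached lower values, 22.6 at Vax1, 18.7 at Ascl1 and 11.2 at Dlx2, a homeobox gene of the ganglionic eminences. At Dlx2 the replicates' own lists gave 11.7 and 5.99. Of 22 genes of the diencephalon, hypothalamus and optic vesicle, 19 were marked, which did not pass the test (adjusted exact p = 0.0934), with Tcf7l2 at 44.1, Lhx5 at 19.5 and Foxd1 at 16.2 and no replicated promoter peak at Barhl1, Otp or Vsx2. With a window at each gene's 5′ end alone this list passed (adjusted exact p = 0.0407).

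Promoters of genes for signalling, dividing cells and newborn neurons were also marked above the share of other genes. Marked members numbered 30 of 31 patterning signal genes (adjusted exact p = 3.44e-04), 22 of 22 cell cycle genes (adjusted exact p = 4.80e-04), 24 of 24 housekeeping genes (adjusted exact p = 3.44e-04) and 18 of 20 newborn neuron genes (adjusted exact p = 0.0446). The signalling genes were led by Gli3, by Axin2 at 43.4, a target of Wnt signalling, and by Ptch1 at 38.8, the Sonic hedgehog receptor, and Wnt1 was the unmarked member. The cell cycle genes Mki67, Ccnb1 and Cdk4 had 41.1, 39.3 and 37.7, and the housekeeping genes Actb, Ywhaz and Gapdh 51.3, 50.2 and 48.5. Among newborn neuron genes, Elavl4 had 34.3, Tubb3 19.4 (19.9 in replicate 1 and 9.31 in replicate 2) and Mapt 18.0, while Neurod4 and Neurod6 had no replicated promoter peak. The remaining 2 lists above the share of other genes belonged to cell types outside the neural tube. Neural crest and mesenchyme genes were marked in 23 of 24 cases (adjusted exact p = 0.00198), with Alx4 at 24.1, Prrx1 at 20.8 and Tfap2a at 19.1 (12.7 in replicate 1 and 25.3 in replicate 2), and no replicated promoter peak at Foxd3. Endothelial genes were marked in 16 of 17 cases (adjusted exact p = 0.0299), with Egfl7 at 14.4, Fli1 at 12.4 and Kdr, a VEGF receptor gene, at 5.65. The endothelial call was lost with either replicate's own peaks alone (82.4% marked, adjusted exact p = 0.248, without replicate 1, and 70.6%, adjusted exact p = 0.801, without replicate 2) and with 5′ ends alone (adjusted exact p = 0.182). The peak at Egfl7 also lay at a TSS of Gm20532. The lists differ in the CpG content of their promoters, and against random lists matched on it 3 lists were above in place of 10. The 4 forebrain lists, cell cycle and housekeeping genes, all at 100%, had no room to pass that test, while patterning signal, neural crest and endothelial genes did not pass it (adjusted permutation p = 0.622, 0.444 and 0.0572). The lists above were newborn neuron genes (90.0% against 70.6%, adjusted permutation p = 0.0484), glia genes (81.3% against 46.3%, adjusted permutation p = 0.00660) and erythroid genes (53.3% against 26.8%, adjusted permutation p = 0.0346).

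Hox, liver, myeloid, heart and olfactory receptor genes were marked less often than other genes. Of 39 Hox genes, which pattern the trunk and hindbrain, Hoxa1 alone had a replicated promoter peak (adjusted exact p = 3.20e-16), with a fold enrichment of 3.59. No replicated promoter peak was found at 15 liver genes such as Alb, Afp and Apoa1 (adjusted exact p = 6.09e-07), of which 13.3% had one in the full list of replicate 1 and 20.0% in that of replicate 2, among them Apoa2 in both lists and Apoa1 in replicate 2 at 2.43. Of the myeloid genes, 12 of 14 had no replicated promoter peak, with Csf1r at 3.78 and Spi1 at 3.02 as the marked pair (adjusted exact p = 3.44e-04). Heart genes were marked in 6 of 16 cases (adjusted exact p = 0.0446), including Myh7 at 16.2 and Ryr2 at 5.95 and not Nkx2-5, Tnni3 or Myh6. The heart call was lost with either replicate's own peaks alone (43.8%, adjusted exact p = 0.103, without replicate 1, and 37.5%, adjusted exact p = 0.0547, without replicate 2), with windows of 2 kb (56.3%), with 5′ ends alone (adjusted exact p = 0.0575) and with pooled peaks (75%), which also ended the myeloid call (42.9%, adjusted exact p = 0.0589). Of 1135 olfactory receptor genes, 5 were marked (0.441%), with Olfr658 highest at 4.72. Midbrain and hindbrain genes (11 of 19), mature neuron and synapse genes (17 of 20), glia genes (13 of 16), surface ectoderm and epithelium genes (10 of 14), erythroid genes (8 of 15) and skeletal muscle genes (7 of 14) did not pass the test, though skeletal muscle genes passed without replicate 1 (35.7%, adjusted exact p = 0.0402). Among midbrain and hindbrain genes, En1 and Pax8 had promoter peaks in replicate 2 alone, at 3.49 and 3.29, and Tal2 led the marked genes at 11.4. Mylpf led the skeletal muscle genes at 24.5, at a peak that also lay at a TSS of Tbc1d10b. With random lists matched on CpG content, 5 lists were below, namely midbrain and hindbrain genes (57.9% against 96.1%, adjusted permutation p = 0.00147), Hox, liver, heart and olfactory receptor genes, and the myeloid call was lost (adjusted permutation p = 0.706).

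**Figure D2:**
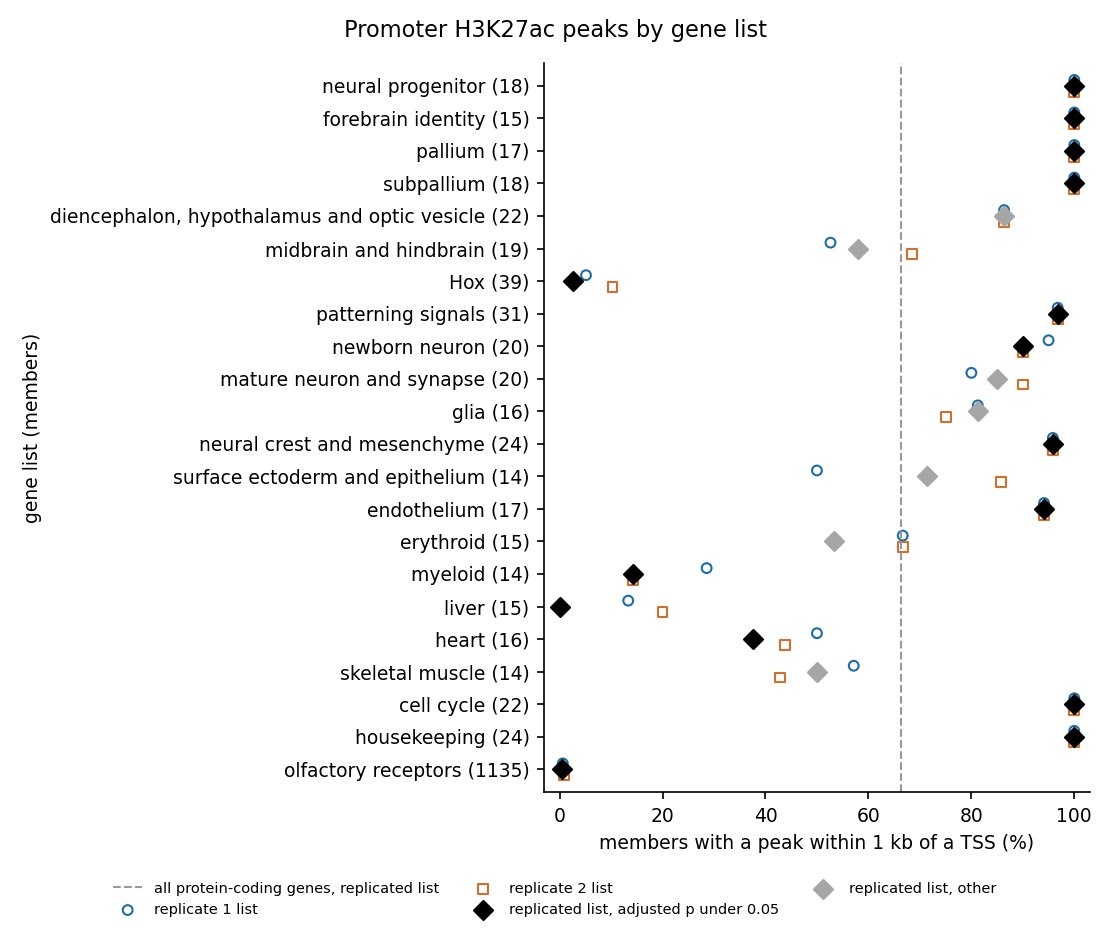
The percentage of members with a peak within 1 kb of a TSS (horizontal axis) is shown for each gene list (vertical axis, members in brackets) in the replicated list (diamonds, black where the adjusted p is under 0.05) and in the full lists of replicate 1 (circles) and replicate 2 (squares). The 4 leading forebrain lists stand at 100%, Hox genes at 2.56% and olfactory receptors at 0.441%, with the dashed line at 66.2% for all protein-coding genes.

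Marked promoters differed in strength between lists, with progenitor and forebrain identity genes among the strongest and genes of other cell types mostly weak. The median promoter fold enrichment was 34.4 in neural progenitor genes (adjusted permutation p = 9.50e-04), 30.96 in housekeeping genes (adjusted permutation p = 9.50e-04), 28.5 in forebrain identity genes (adjusted permutation p = 0.0124) and 28.3 in cell cycle genes (adjusted permutation p = 0.00422), against 17.2 over all marked genes (two-sided permutation test with 10000 random lists of marked genes, Benjamini-Hochberg over 19 lists with at least 3 marked genes). Pallial genes at 23.0 did not pass the test (adjusted permutation p = 0.184), nor did patterning signal genes at 17.1 (adjusted permutation p = 0.975). The other 13 lists lay below. Subpallial genes had a median of 7.44, diencephalic and optic genes 6.30, newborn neuron genes 7.60, mature neuron and synapse genes 5.04 and midbrain and hindbrain genes 3.91. Medians outside the neural lineages were 10.3 in neural crest and mesenchyme, 5.83 in erythroid, 4.19 in surface ectoderm, 4.11 in skeletal muscle, 3.76 in heart and 3.34 in endothelium, and that of glia was 3.18, with Gja1 highest at 28.0. The 5 marked olfactory receptors had a median of 2.98. In glia, neural crest and skeletal muscle the call was lost with replicate 2 peaks alone (adjusted permutation p = 0.0512, 0.0594 and 0.2), and in skeletal muscle also with replicate 1 peaks alone (adjusted permutation p = 0.0767), where the pallial list passed (adjusted permutation p = 0.0493). The neural crest call was also lost with pooled peaks (adjusted permutation p = 0.0634). By the sum of fold times length, patterning signal genes stood at percentile 99.99 (adjusted permutation p = 0.00109), pallial genes passed, and the diencephalic and newborn neuron calls were lost (adjusted permutation p = 0.255 and 0.198). Matched on promoter CpG content, the call of forebrain identity genes was lost (adjusted permutation p = 0.0692), as were those of erythroid, heart and skeletal muscle genes (adjusted permutation p = 0.795, 0.135 and 0.0505).

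Genes of neural progenitors, of the pallium and of patterning signals collected about 3 times as many distal H3K27ac peaks as other genes with similar surroundings. Distal peaks, those overlapping no window of 1 kb around a protein-coding TSS, made up 80.9% of the replicated peaks (71312), and 55052 of these lay within 100 kb of the TSS to which they were assigned. Neural progenitor genes had a mean of 15.2 distal peaks per gene against 4.45 in random lists matched on the length of the territory nearest to a gene (adjusted permutation p = 0.0044). Pallial genes had 13.1 against 4.52 (adjusted permutation p = 0.0143) and patterning signal genes 14.3 against 4.23 (adjusted permutation p = 0.0022). The members of these lists named above had 15 distal peaks at Msi1, 26 at Cdh2, 1 at Zic2, 25 at Gli3, 18 at Pax6, 8 at Emx2, 31 at Axin2, 15 at Ptch1 and 3 at Wnt1. Distal peaks were fewer than in matched lists at Hox genes, with a mean of 0.128 against 0.713 (adjusted permutation p = 0.0334), and at olfactory receptor genes, with 0.039 against 0.899 (adjusted permutation p = 0.0022). The Hox call was lost when distal peaks had to lie 2.5 kb from any TSS (adjusted permutation p = 0.143) or were merged within 1 kb (adjusted permutation p = 0.179). Forebrain identity genes at 8.27 against 5.05, subpallial genes at 6.94 against 3.63 and diencephalic genes at 9.0 against 5.04 did not pass the test (adjusted permutation p = 0.388, 0.213 and 0.213), and neither did the other 14 lists. The genes with the most distal peaks were Gse1 with 116, Casz1 with 94, Zfp423 with 90, Maml3 with 88, Prex1 with 83, Zmiz1 with 78, Tspan18 and Foxp1 with 71 each, Tcf7l2, a transcription factor gene of Wnt signalling, with 70, and Ephb2, an ephrin receptor gene, with 68.

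**Figure D3:**
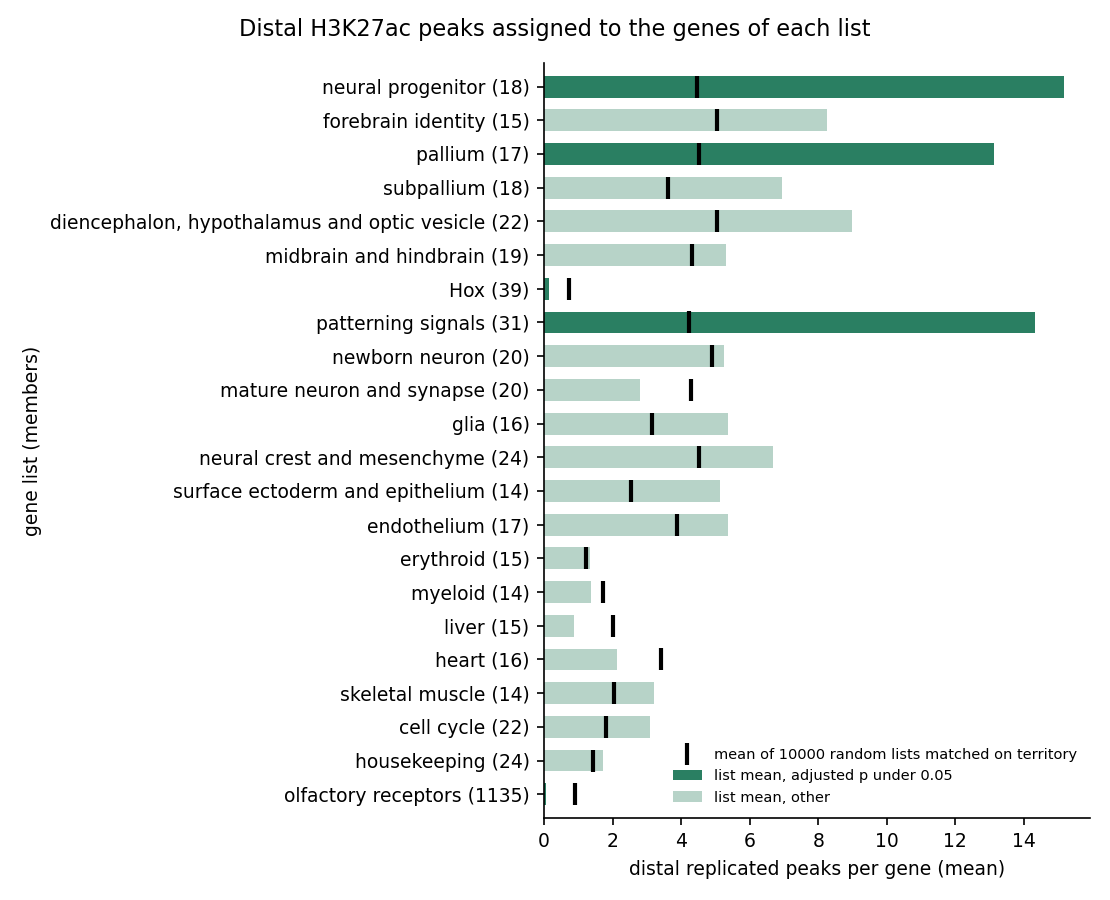
Bars give the mean number of distal replicated peaks per gene (horizontal axis) for each gene list (vertical axis, members in brackets), dark where the adjusted p is under 0.05, and vertical ticks give the mean of 10000 random lists matched on territory. Neural progenitor, patterning signal and pallial genes reach 15.2, 14.3 and 13.1 peaks per gene, against 4.45, 4.23 and 4.52 in random lists.

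Wide domains of H3K27ac lay at forebrain regulators far more often than other domains did. Replicated peaks at most 10 kb apart were joined into 31185 domains, and the 500 with the most bases covered held 21.5% of all covered bases. A TSS of a forebrain list gene lay in 22 of these 500 domains (4.40%) and in 58 of the other 30685 (0.189%), an odds ratio of 24.3 (p = 2.35e-21, Fisher's exact test, two-sided). By list, 11 of the 500 held a neural progenitor gene, 11 a forebrain identity gene, 3 a pallial gene, 1 a subpallial gene and none a diencephalic gene (adjusted exact p = 1.20e-14, 4.57e-16, 0.0130, 0.557 and 1). Lhx2, Pax6 and Emx2, the 3 pallial genes, are also members of the neural progenitor or forebrain identity lists, so the pallial call rests on domains already counted there. Patterning signal genes were in 10 of the 500 (odds ratio 32.9, adjusted exact p = 1.15e-10), of which that of Notch1, also a neural progenitor gene, is among the 22, and no other list passed. Wide domains have more room for any TSS. Among domains with a protein-coding TSS alone, a comparison chosen after seeing the data, the share of the widest with a forebrain list gene was 5.61% (exact p = 8.21e-15). Domains were not matched on the number of TSSs they hold or on the territory of the genes. That comparison therefore does not remove the advantage of wide domains. Chosen after the values were seen, examples are the domain at Notch1 (chromosome 2, 26458409 to 26591259), with 77.8 kb covered, that at Sox2 (chromosome 3, 34634428 to 34680828), with 40.5 kb, and that at Foxg1 (chromosome 12, 49372626 to 49410711), with 31.2 kb. The widest domain lay at Zfp36l1, an mRNA decay factor gene, where 217 peaks covered 284 kb (chromosome 12, 79641302 to 80151301). The next held TSSs of Gse1, Gins2 and 1190005I06Rik, with 247 kb covered (chromosome 8, 120249464 to 120648291). The third held no protein-coding TSS and lay wholly inside the body of Msi2, a paralogue of Msi1 (chromosome 11, 88347765 to 88651123, 163 kb covered). The other 7 of the 10 widest held TSSs of Mn1, of Cstad, Ntmt1 and 1700001O22Rik, of Sulf2, of Mest with 7 neighbours that include Cpa1 and Cep41, of Kif26a, of Prdm16, and of Tspan18 with Trp53i11. Around Emx2, a peak of 17.0 kb spanned the whole gene in the replicated list (chromosome 19, 59453351 to 59470374), and 16 replicated peaks covered 32.5 kb of the surrounding 300 kb. Across 180 kb around the Hoxa cluster, 1 replicated peak covered 0.48 kb (chromosome 6, 52158491 to 52158973).

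**Figure D4:**
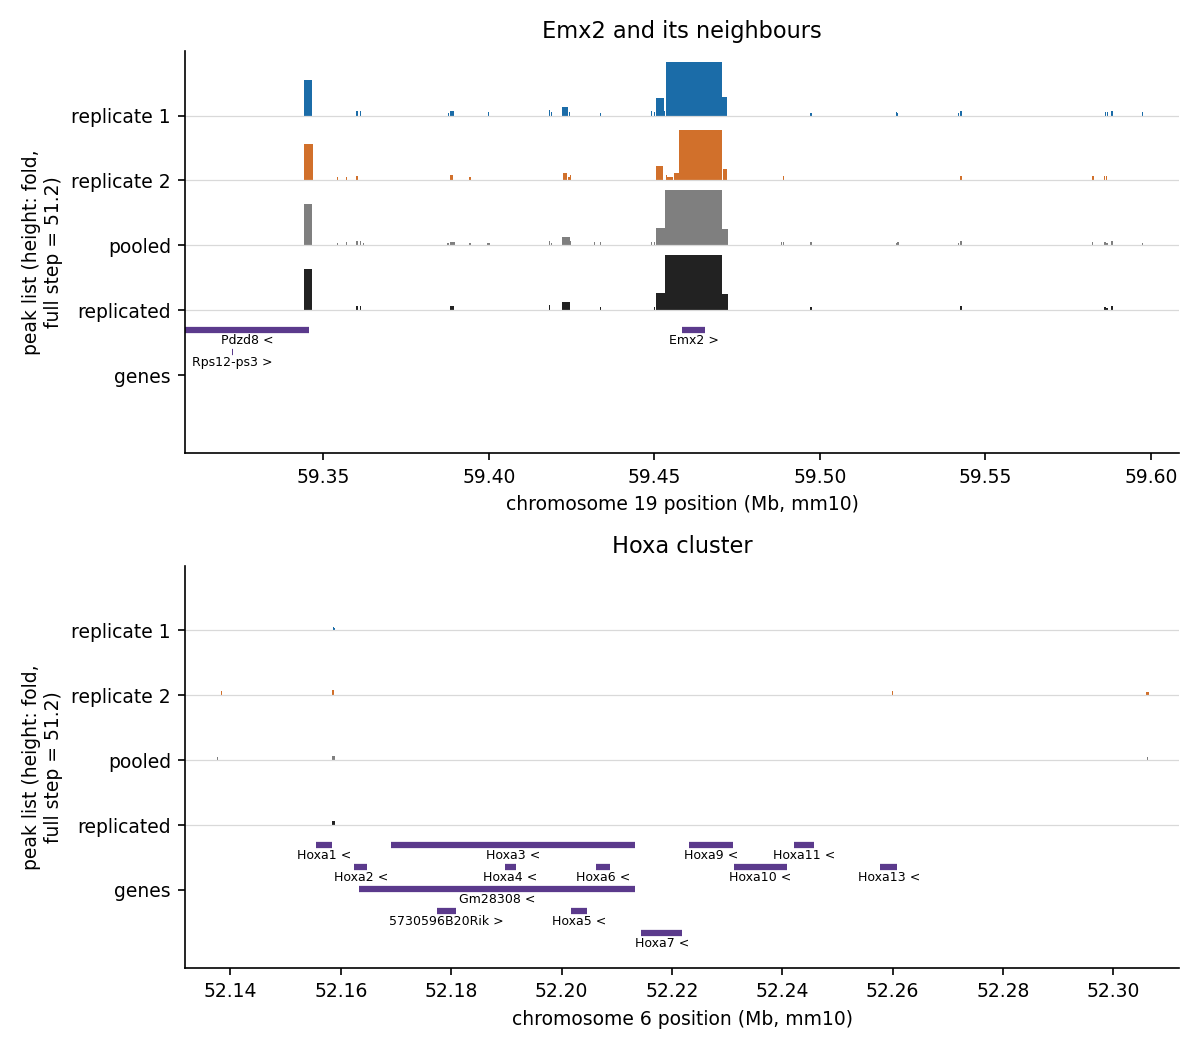
Maps of 300 kb around Emx2 on chromosome 19 and of 180 kb around the Hoxa cluster on chromosome 6 show position in Mb (horizontal axis, mm10) and, for each of the 4 peak lists, peaks as bars whose height is the authors' fold enrichment on the same scale in both maps, above the protein-coding genes. The replicated list holds 16 peaks reaching 43.5-fold around Emx2 and 1 peak of 3.59-fold in the Hoxa region.

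No call was made for any gene list on promoters marked in only 1 replicate, in a test with little room to show a difference. With each replicate's list limited to its 88194 peaks of highest −log10 p, the exact McNemar test found 0 of 22 lists past the threshold, and 0 at an unadjusted p under 0.05. The lowest p was that of surface ectoderm and epithelium genes, of which 0 were marked in replicate 1 alone and 5 in replicate 2 alone (p = 0.0625, exact McNemar test), the smallest p that 5 genes can give. Apart from glia, every list had at most 5 genes marked in 1 replicate alone, and the neural progenitor, forebrain identity, pallial, cell cycle and housekeeping lists were fully marked in both. Over all protein-coding genes, 284 were marked in replicate 1 alone and 606 in replicate 2 alone (exact p = 1.41e-27), so more promoters stood among the strongest peaks of replicate 2. In a test added after this result, the promoter ranks of pallial genes were 13.7 percentile points lower in replicate 2 (a shift of −13.7), and those of neural crest and mesenchyme genes 10.9 points higher. The peaks of highest −log10 p in replicate 1 that no replicate 2 peak overlapped lay nearest 2410131K14Rik (2 peaks), Nfix, Slc26a8 and Pou3f2, with fold enrichments from 6.12 to 6.71. Those of replicate 2 lay nearest Slc22a22, Gm21863, Cdh11, Pax5 and Tmprss2, with fold enrichments from 5.51 to 7.60. The one near Nfix, a nuclear factor I gene, lay at a promoter (chromosome 8, 84773647 to 84774819).

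Distal peaks were richer in the neural bHLH E-box (CAGMTG, the site of proneural factors such as Neurog2 and Ascl1) and in SOX sites than their flanks. Windows of 250 bases to either side of the summit were compared with windows 3 kb away for 59268 peaks. The E-box was present in 59.3% of peak windows and 48.9% of flanks (adjusted exact p = 5.49e-283, exact McNemar test, two-sided, Benjamini-Hochberg over 18 motifs), and the SOX consensus AACAAWG in 21.7% and 18.7% (adjusted exact p = 1.64e-38). The TEAD consensus was present in 27% and 24.8% (adjusted exact p = 5.64e-17), the CTCF core in 1.02% and 0.317% (adjusted exact p = 4.45e-52), and the SP/KLF consensus GGGCGGG in 9.0% and 2.99%. In all, 10 motifs were more frequent in peaks, the others being ETS, GLI, RFX, AP-1 and NFI. Another 6 were less frequent, including the homeodomain core TAATTA at 9.08% and 13.0% (adjusted exact p = 3.52e-105) and the OTX consensus at 13.4% and 19.2%. Peak windows had a GC content of 51.1% and flanks 45.0%, and the part of this difference in each motif result was not isolated. Read backwards without complementing, as a control for base composition, the E-box consensus was less frequent in peaks (12.8% against 19.3%), the homeodomain core was less frequent still than in its forward form (ratio 0.617 against 0.697), and GGGCGGG is unchanged by reversal, so it has no such control. For the CTCF core, ETS and GLI the reversed consensus was also more frequent in peaks, with ratios of 2.67, 1.35 and 1.34 against 3.23, 1.70 and 1.57 for the forward form. The reversed CTCF core was present in only 0.027% of peak windows and 0.01% of flanks, so its ratio rests on few windows. Reversal keeps the bases of a consensus but not its CpG dinucleotides. The ETS consensus loses its CpG, and a form of the reversed E-box gains one, so this control does not cover CpG content. Against shuffled peak windows that keep dinucleotide counts, 11 motifs changed direction. They include all 6 that were less frequent than in flanks, and TAATTA was 2.22 times as frequent in peaks as in shuffles. RFX, NFI, GLI and AP-1 had ratios under 1 there, of 0.775, 0.836, 0.839 and 0.859. Of the motifs that changed direction, NFI and GATA (ratio 1.02) did not pass the threshold against shuffles (adjusted exact p = 0.479 and 0.501). The E-box and SOX ratios there were 1.13 and 1.41. Within 100 bases of the summit the SOX excess was lost, with a ratio of 0.998, as were those of RFX (0.987), AP-1 (0.998) and CTCF (0.937). The NFI call was lost without either replicate, and those of FOX and MEF2 without replicate 1 (adjusted exact p = 0.0650 and 0.664).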

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

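Outside the 21 chromosomes on which all comparisons were made, the replicated list held 10 peaks on unlocalized or unplaced scaffolds. This drew attention because it is a signal in data that no comparison used, and no control libraries were used here to set it against. The largest number was 4 peaks on an unlocalized scaffold of chromosome X, with a highest fold enrichment of 6.47, and the strongest was 1 of 2 peaks on an unlocalized scaffold of chromosome 4, at 39.2. The lists of replicate 1 and replicate 2 each held 11 peaks on scaffolds, reaching 35.9 and 36.8. No explanation was tested.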

How the results depend on the processing

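Alternatives chosen after seeing the data were peaks found in both replicates' lists, domains with a protein-coding TSS, distal peaks away from any annotated TSS and the CpG match for promoter strength. Counts and main shares moved under an alternative in 7 cases, and otherwise kept their direction, with counts within 1.5 times the main count. With pooled peaks of −log10 q of at least 2, the replicated share was 54.8% in place of 46.6%, as fewer weak peaks entered. With pooled peaks, 3 lists in place of 5 were marked less often. Matched on promoter CpG content, 3 lists in place of 10 were marked more often, where 6 of the 10 were at 100% and had no room to pass. Without matching on territory, 6 lists in place of 3 had more distal peaks, which the simulated lists at chance also show. With distal peaks 2.5 kb from any TSS or merged within 1 kb, 1 list each in place of 2 had fewer. Within 100 bases of the summit, 5 motifs in place of 10 were more frequent. The other causes were not tested. Among values of individual lists and motifs, 616 were the same, 36 lost and 11 gained their call, and 43 reversed.

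Reversed shares of marked promoters were 56.3% in glia without replicate 1, 62.5% with windows of 500 bases and 56.3% at 5′ ends alone, with a leave-one-out range of 56.3% to 68.8%. In surface ectoderm they were 50% without replicate 2 (leave-one-out range 50% to 85.7%), 50% with peaks found in both replicates' lists, 64.3% with windows of 500 bases and 71.4% matched on CpG content. In erythroid genes they were 73.3% with pooled peaks and 53.3% matched on CpG content, in heart genes 75% with pooled peaks, and in diencephalic genes 86.4% matched on CpG content. The median promoter fold enrichment of patterning signal genes reversed to 16.3 and 17.8 with the peaks of replicate 2 and replicate 1 alone, 16.5 with pooled peaks and 17.7 with peaks found in both lists. By the sum of fold times length, these genes stood at percentile 99.99 and neural crest genes at percentile 65.9. Introns held 41.9% of peaks found in both lists. Distal peaks per gene reversed in erythroid genes at 1.07 without replicate 1 (leave-one-out range 1.07 to 1.27), 1.00 with peaks found in both lists, 1.33 without matching and 1.07 away from TSSs by 2.5 kb. They reversed in mature neuron genes at 2.80 and housekeeping genes at 1.71 without matching, in myeloid genes at 1.36 within 50 kb and 3.21 within 1 Mb, and in midbrain and hindbrain genes at 5.79 within 1 Mb. Motif ratios reversed to 0.999 for NR2F without replicate 2 (leave-one-out range 0.999 to 1.02), and within 100 bases to 0.998 for SOX, 0.987 for RFX, 0.998 for AP-1 and 0.937 for CTCF. Against dinucleotide shuffles they were 2.22 for the homeodomain core, 1.10 for OTX, 1.65 for POU, 0.775 for RFX, 0.836 for NFI, 0.910 for NR2F, 1.75 for FOX, 0.839 for GLI, 0.859 for AP-1, 1.02 for GATA and 2.495 for MEF2. The cause of these reversals was not tested. No paired analysis was possible because the series has 1 group. The agreement of the replicates needs both, so no replicate was left out of it. Depth is unknown, so absence of a peak does not show absence of the mark.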

Other observations

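The distal peaks described first, the test of promoter ranks, the tests of noise acting through rank and of cells outside the neural tube, and the test of gene density on chromosome X were chosen after the results were seen. Some strong distal peaks lay at genes that do not code for proteins, a pattern not tested for enrichment. Of the 71312 distal peaks, 3243 (4.55%) had a further annotated TSS within 1 kb of the summit, with a median fold enrichment of 3.49 against 3.13 for the others. These further TSSs can include 5′ ends of protein-coding genes that are not among the TSSs of protein-coding transcripts. The 3243 is therefore not a count of genes that do not code for proteins. Of the 20 strongest distal peaks, 9 had the TSS of a gene annotated as other than protein-coding within 1 kb of the summit. Those at the microRNA gene Mirlet7i (chromosome 10, 122983737 to 122987270), at Snhg6 and at Dleu2 had fold enrichments of 48.6, 42.6 and 43.8, and one 1.28 kb from Mir17hg, the host of a microRNA cluster, had 42.8 (chromosome 14, 115040106 to 115043443). A peak of 21.8 kb with a fold enrichment of 44.9 lay 77.9 kb from the TSS of Mef2c and 1.2 kb from that of the long noncoding gene Gm26803 (chromosome 13, 83712780 to 83734572).

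Promoters of 6 lists, led by pallial genes, ranked lower in replicate 2 than in replicate 1, and those of neural crest and surface ectoderm genes ranked higher. This was tested after the planned exact test of marking had called 0 of 22 lists, with 0 at an unadjusted p under 0.05. Ranks of fold enrichment were taken over the 13820 genes with a promoter peak among the 88194 strongest peaks of both replicates, and 18 lists were compared with random genes of similar mean rank. Pallial genes shifted by −13.7 percentile points on average, with 0 of 17 members higher in replicate 2 (adjusted permutation p = 0.0009). Percentiles in replicates 1 and 2 were 85.8 and 57.1 for Dmrt3, 39.9 and 11.9 for Wnt8b, and 44.3 and 19.1 for Neurog2. Neural progenitor, forebrain identity, diencephalic, patterning signal and newborn neuron genes passed with −7.39, −6.50, −7.50, −6.10 and −6.98 points, and their members were mixed, with 2 of 18, 3 of 15, 5 of 18, 11 of 28 and 6 of 18 higher in replicate 2. Neural crest and mesenchyme genes shifted by 10.9 points, with 19 of 23 members higher in replicate 2 (adjusted permutation p = 0.0009), among them Tfap2a (37.9 and 74.4) and Tfap2b (21.9 and 48.8). Surface ectoderm genes shifted by 6.65 points (5 of 7 members higher, adjusted permutation p = 0.0121). The other 10 lists tested did not pass, with −1.71 points in subpallial, −1.32 in mature neuron, 2.84 in midbrain and hindbrain, 1.26 in glia, −0.413 in endothelial and −2.41 in erythroid genes.

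Noise or call depth acting through rank alone would shift a list no more than random genes of like mean rank, which 8 of the 18 lists exceeded (also with a match on promoter CpG content). That is the same comparison that found the shifts, so it is not a separate test, and some genes stand in more than 1 of these lists. Effects of depth that act in another way were not tested. A larger share of all cells outside the neural tube in replicate 2 met the criterion first set for it, as surface ectoderm and neural crest genes both ranked higher. The criterion was then reworded, after the values were seen, to ask that endothelial and erythroid genes shift alike. These shifted by −1.19 points over 18 genes against 10.9 over 23 neural crest genes (permutation p = 6e-05, two-sided). Above the lowest 10% of mean rank the shifts were −0.147 over 8 genes against 12.5 over 19 (permutation p = 0.00332). Endothelial and erythroid genes thus shifted less than neural crest genes. Because the outcome was known when the criterion was reworded, and genes were not matched on rank, this does not decide the explanation. Different input libraries, if the further files noted for the lists are such and the notes are complete, cannot be told apart from other causes, because the median shift of neighbouring genes was bounded under 50% of the members' median shift in 0 of 8 lists (against the members' mean, in patterning signal genes alone), and in the 1 list whose neighbours' median reached it (forebrain identity, −6.41 points) the interval ran from −13.4 to 6.11. A larger share of mesenchyme and surface ectoderm cells alone was not tested, nor were differences in dissection or stage, and the neural lists did not all shift, with −13.7 points in pallial and −1.71 in subpallial genes, a difference that was not tested.

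Chromosome X carried few replicated peaks, 6.86 per Mb against 25 to 56.2 on the autosomes, in embryos pooled across sexes. Lower gene density is not enough, since 48.2% of X genes were marked against 67.6% of autosomal ones, a ratio of 0.713. Promoter CpG content is not enough either, since the X share differed from the mean of CpG-matched autosomal lists by −8.92 percentage points and was lower than all 10000 of them. A weaker signal per locus from 1 active copy may contribute but was not decided. The median promoter fold enrichment on X was 0.814 of that of matched autosomal genes, and at 11.7 lay above the lowest matched value, 11.5. Over all replicated peaks the median was higher on X, at 5.03 against 3.285 on autosomes. These medians cover different mixes of peaks. On X, 666 of 1174 peaks were distal, against 80.9% of all replicated peaks, and distal peaks had a median of 3.16 against 12.3 for the others. The higher median on X therefore does not show a stronger signal per locus. Halving the autosomal −log10 p left 1.51 times as many peaks per gene as on X, over the bound of 1.5 set before the test. The calling limit of 5.36 (the 5th percentile on X) had not been set before the test. Mappability and repeats on X were not tested.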
